A study of Mus musculus with 6 samples.

How the data were processed

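Retinas of C57Bl6/J wild-type (WT) and rd10 mice were collected at postnatal day 30, with 2 frozen retinas per sample and 3 samples per group, per the labels. Total RNA was extracted with a column kit that includes DNase treatment, and strand-specific libraries were made from 1 µg of it with a modified TruSeq protocol in which the uracil-marked cDNA strand is degraded before sequencing, per the labels' protocols. Per the submitters' processing notes, TopHat2 2.1.0, HTSeq and edgeR were used with the mm10 build; the notes give neither the role nor the order of the tools, and the annotation is not given in the sources used here. The authors deposited whole-number gene counts, not normalized, in a table of 6 library columns. The numbers in the column names match no replicate number of the samples' titles, so columns were assigned to WT or rd10 by name and kept their own names (WT-1, WT-4, WT-23, Rd10-3, Rd10-4, Rd10-5). The authors also deposited 2 gene tables with 1 FPKM value per group, a log2 fold change of rd10 over WT and a p-value, per the file headers; how FPKM values were averaged and how genes were selected for the smaller table are not given in the sources used here. On the files themselves, no gene of either table had a p of 0.05 or more or an FPKM under 2 in both groups. The deposited log2 fold changes, p-values and FPKM values were used as they stand, with no new test of single genes. The directions of the deposited fold changes entered the tests of protein classes in the closing part.

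The count table held 24062 genes, 5857 of them at 0 in every library, with no totals of unassigned reads and no mitochondrial genes. Library totals ran from 13573035 to 15818918 counts in WT and from 10923556 to 12171088 in rd10. Libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom between 7.67 and 60.9 for pairs within groups, so none was treated as a copy of another. Genes were filtered with filterByExpr, which left 13905, and tested in R 4.3.3 with edgeR 4.0.16 (TMM factors, robust quasi-likelihood fit, genotype as the only term) with Benjamini-Hochberg adjustment and a threshold of 0.05. Errors of log2 fold changes are standard errors from that fit; CPM values are TMM-scaled and given as mean ± SD of 3 libraries. TMM factors ran from 0.902 to 0.933 in WT and from 1.08 to 1.10 in rd10.

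For the gene tests, 27 gene lists were fixed before the data were examined, as were the samples, the tests, the rule for named genes and most alternatives. The lists covered rod, cone, outer segment and cilium, Müller, gliosis, Hippo, YAP/TEAD target, microglial, complement, antigen presentation and interferon, cytokine, trophic, bipolar, amacrine, horizontal, ganglion, astrocyte, vascular, pigment epithelium, lens, blood, cell cycle, cell death, immediate early, cholesterol, oxidative phosphorylation and glycolysis genes. Lists with at least 3 tested members (26 of them) were tested with camera in limma 3.58.1, two-sided, with a preset correlation of 0.01 and adjustment over the lists, and again with an estimated correlation and with fry, whose directional p asks whether a list's genes move one way and does not compare them with other genes. With the preset correlation 16 lists were called, 14 higher and 2 lower, with an estimated correlation 2, and by fry 21. Shares of counts and differences between list means, on log2 CPM with a prior count of 2, were compared with exact two-sided permutation tests (scipy 1.17.1), which with 3 against 3 cannot give a p under 0.1; inner neuron genes are the bipolar, amacrine and ganglion cell lists.

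The genes named by rule were 10 set in advance, the 6 largest called rises and falls among genes with a mean of at least 5 CPM and groups that do not overlap, predicted genes left out, and up to 3 called members per list with the smallest p, or the 2 most abundant where none was called. This gave 78 genes, not all of which are printed; any other gene is said to be chosen after its values were seen or is listed because it completes a count. Transcript GC content and positions came from GENCODE M21 (GRCm38, the assembly that mm10 names). Of the genes matched to it, 99.97% lay on the chromosome given in the authors' deposited table and 69.21% had identical start and end.

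The fit was tested on simulated data, with counts drawn for the 13905 filtered genes from the means and sizes of these libraries. In it 200 genes were changed at random, up or down, with no GC trend and no joint fall of rod genes put in, unlike the real data. After filtering, 13765 genes were left. Of these, the fit recovered 7.895% of 76 genes changed 1.5-fold, 54.1% of 61 changed 2-fold and 91.53% of 59 changed 4-fold. There were 9 false calls (8.824% of calls) and none in the wrong direction. Alternatives were DESeq2 1.42.0, limma voom, other scaling factors (RLE, upper quartile, library size alone, inner neuron lists, photoreceptor genes left out), other filters and thresholds, and each library left out in turn. After seeing the data, fits with a loess trend on GC content removed per library (span 0.3; 95.49% of tested genes had a GC content, and the others, Ctgf and Cyr61 among them, were not corrected), with a factor for Y-linked counts, without WT-1 and Rd10-4, and with shared list members or Nt5e and Lats2 left out were added. Results of the alternatives are in the closing part.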

Results

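RNA-seq was used to compare whole retinas of wild-type C57Bl6/J mice (WT) with those of rd10 mice at postnatal day 30. The rd10 mouse carries a missense change in Pde6b, which encodes the beta subunit of the rod phosphodiesterase, and loses its rods in the weeks after birth. Each group held 3 libraries, each made from 1 sample of 2 frozen retinas. The study's title places the question in Müller cells, the main glia of the retina, and in YAP and TEAD, the coactivator and DNA-binding proteins at the end of the Hippo pathway. The counts assigned to genes came to 13573035 in WT-1, 15499436 in WT-4, 15818918 in WT-23, 11817295 in Rd10-3, 10923556 in Rd10-4 and 12171088 in Rd10-5. The libraries are named here as in the count table. The 10 most abundant genes took 11.9 ± 0.82% of the counts in WT and 6.19 ± 0.34% in rd10 (SD, n = 3 libraries per group). The ribosomal RNA precursor Rn45s took between 0.666% and 0.689% of the counts in the WT libraries and between 1.04% and 1.08% in the rd10 libraries. The labels do not say whether the samples of a group came from separate animals, so p-values measure the spread between these samples.

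In rd10 retinas, genes of rod phototransduction fell, while most tested genes of the gliosis, complement and microglial lists rose. Pde6b itself went from 3229 ± 221 to 757 ± 216 CPM (counts relative to the TMM-scaled library size; SD, n = 3 per group), a log2 fold change of -2.09 ± 0.20 (SE; edgeR quasi-likelihood test, adjusted p = 0.000726). Because its rd10 allele is a missense change, its count does not check the labels. The gene with the largest fitted rise among those named by rule was Timp1, a metalloproteinase inhibitor, with 3, 0 and 3 counts in the WT libraries and 151, 160 and 150 in the rd10 libraries. Serpina3n, a protease inhibitor of reactive glia, rose from 10.8 ± 2.7 to 375 ± 54 CPM.

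Across the 13905 genes tested, 2008 had an adjusted p under 0.05 by edgeR's quasi-likelihood test, 990 of them higher and 1018 lower in rd10. Changes of more than 2-fold were called for 566 higher and 418 lower genes, and changes of more than 4-fold for 199 higher and 57 lower genes. The 3 libraries of a group lay wholly on one side of the other group for 4960 genes, or 35.7% of those tested, against 10% by chance. Without WT-1 the number of called genes was 3214, and without WT-4, Rd10-3, Rd10-4 or Rd10-5 in turn it was 952, 885, 1227 and 1317. Removing from each library a trend with transcript GC content, chosen after seeing the data, raised it to 4545, with 1998 of the 2008 genes kept. The balance of rises and falls depended on the scaling. Of the calls, 49.3% were higher in rd10 with TMM factors and 63.3% with upper quartile factors. With library size alone 81.2% of 3037 calls were higher, and with factors from bipolar, amacrine and ganglion cell genes (inner neuron scaling) 14% of 4505. Against TMM, library size alone moved the median log2 fold change of all genes by 0.239 and the inner neuron factors by -0.297, and all changes below are relative to TMM.

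Other large rises were those of C4a and C4b (log2 fold change 5.48 ± 0.33 and 4.58 ± 0.27), near-identical complement genes whose reads the counting could split, so that each value is uncertain. Calca, which encodes calcitonin and the peptide CGRP, rose by 4.59 ± 0.31 on the log2 scale, and Steap4, a metalloreductase, by 4.36 ± 0.31 (adjusted p = 0.000398 for both). Among the genes that fell most were Hdc, the histidine decarboxylase gene, and Glb1l3, a beta-galactosidase relative. Hdc had 126, 194 and 136 counts in WT and 2, 3 and 3 in rd10 (log2 fold change -5.64 ± 0.32, adjusted p = 0.000271). Glb1l3 had 100, 189 and 211 in WT and 2, 0 and 7 in rd10 (-5.60 ± 0.57, adjusted p = 0.000856; -7.05 without Rd10-5). The linker histone gene Hist1h1c (-2.56 ± 0.44), the rod transcription factor gene Nrl (-2.54 ± 0.21) and the photoreceptor guanylate cyclase gene Gucy2f (-2.45 ± 0.29) fell as well. Hist1h1c varied among WT libraries, with 546 counts in WT-1, 260 in WT-4 and 210 in WT-23, against 48, 58 and 58 in rd10, and its log2 fold change was -1.90 without WT-1.

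All 23 rod genes fell in rd10, with a median log2 fold change of -2.09. Gnb1, a subunit of the rod G protein, fell by 2.12 ± 0.16 and the channel subunit gene Cngb1 by 2.26 ± 0.17 (both n = 3 per group, edgeR adjusted p = 0.000423 and 0.000454). Of the 20 genes of the photoreceptor outer segment and cilium, 19 fell (20 adjusted over the list alone), with a median of -1.44. Rdh12, a retinol dehydrogenase gene, fell by 2.02 ± 0.14, the lipid transporter gene Abca4 by 1.63 ± 0.13 and the guanylate cyclase gene Gucy2e by 1.46 ± 0.13. The camera adjusted p was 2.95e-21 for rod genes and 9.71e-16 for outer segment and cilium genes with the preset correlation, and adjusted p = 0.0918 and 0.0915 with an estimated correlation. The rod list's share of all counts was 12.1 ± 0.72% in WT and 3.28 ± 0.59% in rd10 (SD, n = 3 libraries per group; exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 allows).

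Of 14 cone genes, 5 rose (Arr3, Opn1mw, Pde6c, Gnb3 and Cnga3) and 1 fell (Thrb, a thyroid hormone receptor), and adjusted over the list alone 5 rose and 2 fell. Arr3, the cone arrestin gene, rose by 1.40 ± 0.17 on the log2 scale (adjusted p = 0.0015), from 76.9 ± 17.7 to 203 ± 5 CPM, and the middle-wave opsin gene Opn1mw by 0.56 ± 0.13 (adjusted p = 0.0298). The short-wave opsin gene Opn1sw had a log2 fold change of -0.41 ± 0.14 and missed the threshold (adjusted p = 0.0922), but passed it with inner neuron scaling (-0.71, adjusted p = 0.00979). The list's median was 0.29 with TMM and -0.0085 with inner neuron scaling, and its camera adjusted p was 0.0413, or adjusted p = 0.279 with an estimated correlation. That call was lost as well without WT-1, WT-23 or Rd10-4 (adjusted p = 0.0643, 0.0756 and 0.0663), with upper quartile factors (0.0515), with library size alone (0.065) and without both WT-1 and Rd10-4 (0.0624). The call of Opn1mw was lost without WT-4, Rd10-3 or Rd10-5 (adjusted p = 0.0697, 0.138 and 0.095), and that of Pde6c, the cone phosphodiesterase gene (0.60 ± 0.15), without WT-23, Rd10-3, Rd10-4 or Rd10-5 (adjusted p = 0.0654, 0.161, 0.0713 and 0.0709). Neither passed with inner neuron scaling (adjusted p = 0.176 and 0.165), against a fold of 1.2 (0.0949 and 0.101) or with Y-linked counts as a factor (0.0671 for both). Within libraries, the mean log2 CPM of rod genes minus that of cone genes differed between rd10 and WT by -2.28 ± 0.19 (SE, n = 3 per group; exact permutation p = 0.1, the smallest possible). For rod genes minus inner neuron genes the difference was -2.21 ± 0.20 (exact p = 0.1). For cone genes minus inner neuron genes it was 0.063 ± 0.084 (exact permutation p = 0.6, n = 3 per group), within the replicate error.

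Of 16 bipolar cell genes, 6 rose and 1 fell (8 and 1 adjusted over the list alone). Cabp5, a calcium-binding protein gene, rose by 0.61 ± 0.11 and Trpm1, the transduction channel of ON bipolar cells, by 0.51 ± 0.11, while Lrit3, which photoreceptors express as well, fell by 0.92 ± 0.13 (edgeR adjusted p = 0.00778, 0.0153 and 0.00335). Leaving out WT-4 or Rd10-3 ended the call of Cabp5 (adjusted p = 0.0527 and 0.0581), and leaving out WT-4, Rd10-3, Rd10-4 or Rd10-5 that of Trpm1 (adjusted p = 0.0732, 0.0696, 0.0596 and 0.0559). With inner neuron scaling neither gene passed (adjusted p = 0.0906 and 0.155), nor did Trpm1 against a fold of 1.2 (0.0662). Inner neuron scaling takes its factors from the bipolar, amacrine and ganglion cell genes themselves, so it sets their typical change near 0 by construction. For these lists, a call or median lost with that scaling is therefore no separate evidence. All 14 amacrine cell genes had positive fold changes with TMM, but each missed the edgeR threshold over all genes and adjusted over the list alone, the nearest being Pax6 (0.36 ± 0.11, adjusted p = 0.0584). Calb2 and Gad1, the most abundant, had log2 fold changes of 0.32 ± 0.15 and 0.22 ± 0.11. Both passed with the GC trend removed (adjusted p = 0.0157 and 0.0142) and with library size alone (0.0254 and 0.0278), and Gad1 had -0.08 with inner neuron scaling. The camera adjusted p was 0.0032 for bipolar and 0.00739 for amacrine cell genes, against adjusted p = 0.0915 and 0.0918 with an estimated correlation. The amacrine median was 0.27 with TMM and -0.0273 with inner neuron scaling. Among 9 horizontal cell genes Tpm3, a tropomyosin gene of many cell types, rose by 0.76 ± 0.12 (1 adjusted over the list alone). Among 13 ganglion cell genes Gap43, a growth cone protein gene, rose by 0.41 ± 0.11, but missed the threshold adjusted over the list alone, with inner neuron scaling (adjusted p = 0.482), against a fold of 1.2 (0.208), with Y-linked counts as a factor (0.0725) and without WT-4, WT-23, Rd10-3, Rd10-4 or Rd10-5 (adjusted p = 0.181, 0.0521, 0.173, 0.123 and 0.126). The camera adjusted p was 0.22 for horizontal and 0.0753 for ganglion cell genes. By fry, which does not compare a list with other genes, both passed (adjusted p = 0.0149 and 0.0242). The medians of these lists, 0.14 and 0.23, were -0.159 and -0.0671 with inner neuron scaling.

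**Figure D1:**
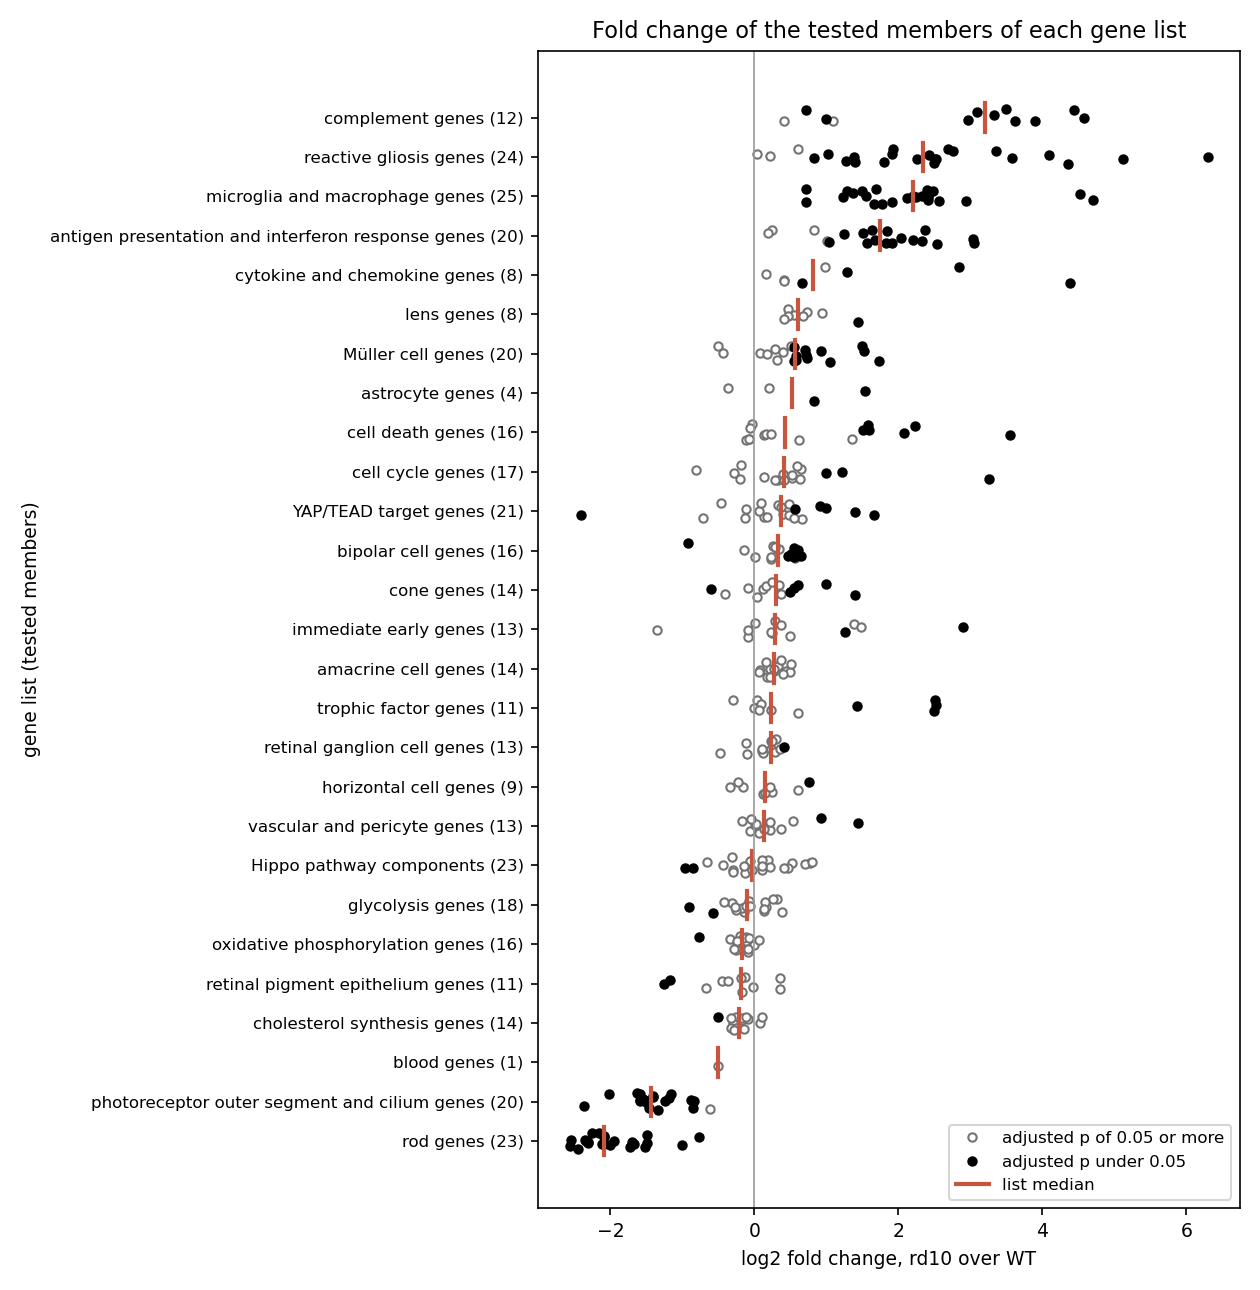
Log2 fold change of rd10 over WT (x axis) for every tested member of each gene list (y axis, number of tested members in brackets), with filled points for an adjusted p under 0.05, open points for the others and a red bar at the list median. Rod genes have a median of -2.09 and complement genes one of 3.21, while the median of the Hippo pathway components is -0.04.

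Of 20 Müller cell genes, 12 rose and 8 were not called (14 rose adjusted over the list alone), with a median log2 fold change of 0.56. Clu, the clusterin gene, rose by 1.72 ± 0.18 from 996 ± 136 to 3290 ± 646 CPM, Crym, a thyroid hormone binding protein gene, by 1.496 ± 0.159 and the caveolin gene Cav1 by 1.06 ± 0.13 (SE, n = 3 per group; edgeR adjusted p = 0.000864, 0.00101 and 0.00151). The most abundant member, the glutamine synthetase gene Glul, went from 4180 ± 206 to 5094 ± 165 CPM, a log2 fold change of 0.29 ± 0.11 that missed the threshold (adjusted p = 0.12), passed it with the GC trend removed (adjusted p = 0.023) and turned to -0.0117 with inner neuron scaling. The list's camera adjusted p was 1.69e-07, or adjusted p = 0.0915 with an estimated correlation. The mean of the Müller list minus that of inner neuron genes was 0.362 ± 0.043 higher in rd10 on the log2 scale (SE, n = 3 per group; exact permutation p = 0.1, the smallest possible), and the list's share of counts was 0.887 ± 0.029% in WT and 1.69 ± 0.15% in rd10 (SD, exact p = 0.1).

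Of 24 tested genes of reactive gliosis, 21 rose (22 adjusted over the list alone), with a median log2 fold change of 2.35. Gfap, the intermediate filament gene that reactive glia induce, rose by 2.69 ± 0.28 (adjusted p = 0.000895), from 55.3 ± 21 to 356 ± 51 CPM. Vim, Stat3, Socs3 and Cd44, chosen after their values were seen, rose by 1.02 ± 0.16, 1.27 ± 0.16, 2.43 ± 0.36 and 2.27 ± 0.17. Nes (0.61 ± 0.21), Ednrb (0.22 ± 0.24) and Hspb1 (0.04 ± 0.38) did not pass the edgeR test over all genes (adjusted p = 0.0983, 0.589 and 0.958). The list's camera adjusted p was 6.97e-19, or adjusted p = 0.0915 with an estimated correlation. Among 11 trophic factor genes, 4 rose (4 adjusted over the list alone), namely Fgf2 (2.50 ± 0.27), Lif (2.51 ± 0.35), Edn2 (2.53 ± 0.37) and Cntf; the first 3 are members of the gliosis list too. The trophic list had a median of 0.23, which was -0.0677 with inner neuron scaling, and a camera adjusted p of 0.00483, or adjusted p = 0.0974 with an estimated correlation, 0.224 without members shared with other lists and 0.0823 among genes with a mean of at least 5 CPM. Of 4 tested astrocyte genes, Aldh1l1, which Müller cells express as well, and Pdgfra rose (1.53 ± 0.22 and 0.83 ± 0.15). The astrocyte list had a camera adjusted p of 0.089 and passed by fry (adjusted p = 0.0122).

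Yap1, which encodes YAP, was higher in each rd10 library than in any WT library but missed the threshold over all genes. It went from 25.6 ± 3.8 to 34.2 ± 2.5 CPM (SD, n = 3 per group), a log2 fold change of 0.42 ± 0.15 (SE; edgeR adjusted p = 0.0986). With the GC trend removed, the value was 0.49 ± 0.10 and passed (adjusted p = 0.00387). Yap1 was also under the threshold without WT-23 (adjusted p = 0.0352), with upper quartile factors (0.048) and with library size alone (0.0189), and its adjusted p ran from 0.00387 to 0.612 over all alternatives. Wwtr1, which encodes the YAP paralog TAZ, had a log2 fold change of 0.11 ± 0.14 and Tead1 one of 0.22 ± 0.20 (adjusted p = 0.66 and 0.503); with inner neuron scaling they had -0.19 and -0.09. Tead2, named after its values were seen, had 0.77 ± 0.28 (adjusted p = 0.102). Of 23 Hippo pathway components, Taok3 and Wwc2, genes of an upstream kinase and of a KIBRA-family scaffold, fell (-0.96 ± 0.13 and -0.86 ± 0.15) and none rose, with the same counts adjusted over the list alone. The list's median was -0.04, its mean 0.00428 and its camera adjusted p 0.779, with a median of 0.199 under library size alone and -0.34 with inner neuron scaling.

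Of the 21 tested targets of YAP and TEAD, 16 had positive fold changes with TMM, while those called moved both ways. Ctgf and Cyr61, matricellular protein genes and the best known targets, rose by 0.92 ± 0.20 and 0.99 ± 0.25 on the log2 scale (SE, n = 3 per group; edgeR adjusted p = 0.0192 and 0.032), from 22.4 ± 4.5 to 42.2 ± 8.2 CPM and from 3.80 ± 1.09 to 7.54 ± 0.78 CPM. Of 21 tested members, 5 rose (Ctgf, Cyr61, Myof, Axl and Tgfb2) and Nt5e fell, with 6 higher and 1 lower adjusted over the list alone. Myof, a membrane repair gene, rose by 1.66 ± 0.13 and Axl, a receptor kinase gene, by 1.39 ± 0.18, whereas Nt5e, a cell surface nucleotidase gene that rods express, fell by 2.41 ± 0.24. The list had a median of 0.37 and a camera adjusted p of 0.00773, or adjusted p = 0.279 with an estimated correlation, and 15 members were not called. Relative to inner neuron genes its mean differed between the groups by 0.0113 ± 0.0663 (SE; exact permutation p = 0.9, n = 3 per group). Without Nt5e and Lats2, left out after their values were seen, this difference was 0.173 ± 0.067 and the list's camera adjusted p 0.000874, and leaving out members that lay below the list's mean raises the difference by construction. The call of Ctgf was lost without WT-4, Rd10-3 or Rd10-4 (adjusted p = 0.0884, 0.0675 and 0.0595). That of Cyr61 was lost without WT-4, Rd10-3, Rd10-4 or Rd10-5 (adjusted p = 0.0916, 0.097, 0.0999 and 0.0786), against a fold of 1.2 (adjusted p = 0.0594) and with inner neuron scaling (adjusted p = 0.0517).

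**Figure D2:**
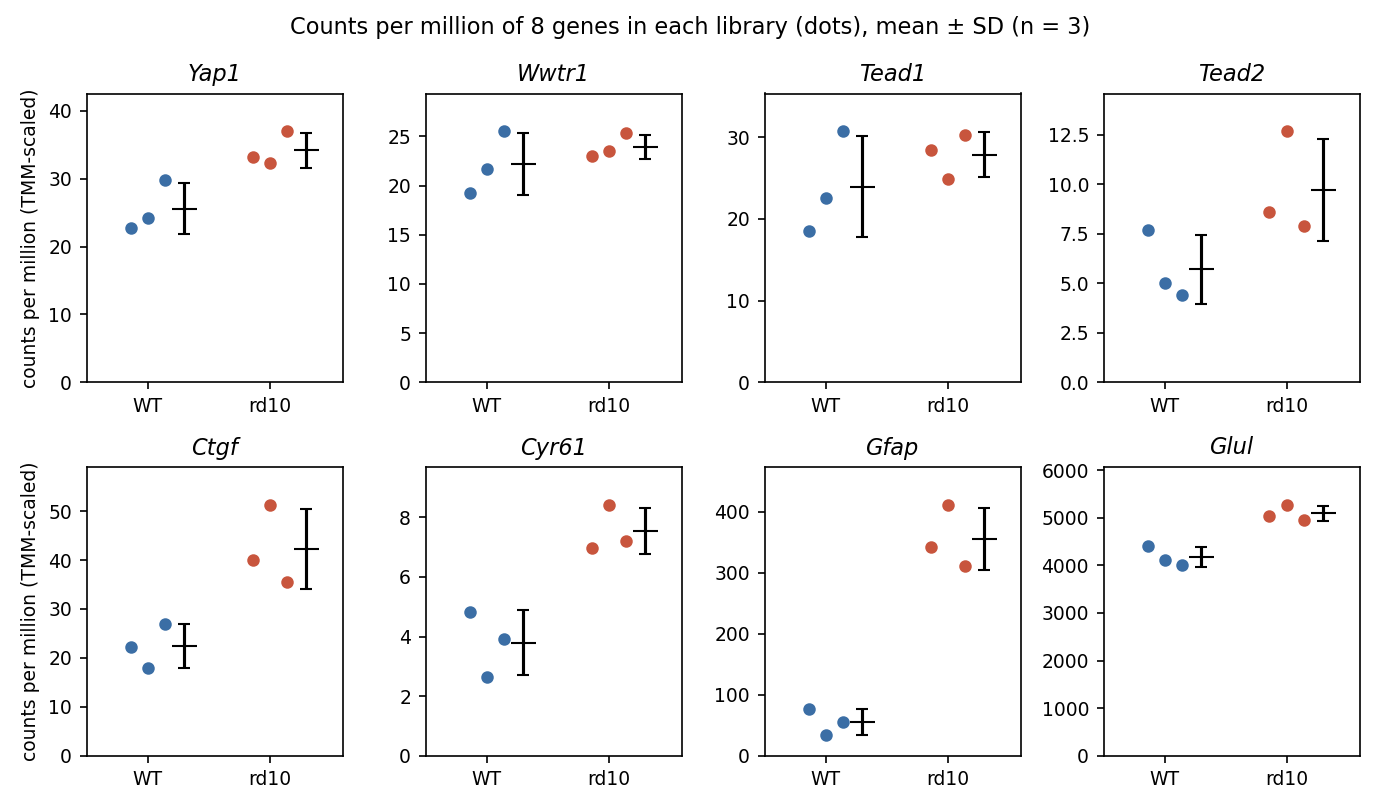
CPM after TMM scaling (y axis) of 8 genes in the WT and rd10 libraries (x axis), with a dot per library and the mean with its SD (n = 3) in black. Yap1 runs from 22.7 to 29.9 in WT and from 32.3 to 37.0 in rd10, Wwtr1 and Tead1 overlap between the groups, and Gfap runs from 34.4 to 76.4 in WT and from 312 to 412 in rd10.

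In mm10 coordinates, the authors' deposited table places Yap1 on chromosome 9 from 7931999 to 8004596, Ctgf on chromosome 10 from 24595442 to 24598683 and Cyr61 on chromosome 3 from 145646976 to 145649981. In the same authors' deposited table Pde6b lies on chromosome 5 from 108388391 to 108432397 and Gfap on chromosome 11 from 102887336 to 102900912, and all 5 are protein coding genes there.

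All 25 genes of microglia and macrophages rose, with a median log2 fold change of 2.20. Itgam, the integrin CD11b, rose by 2.12 ± 0.17 from 4.21 ± 0.40 to 18.3 ± 2.3 CPM and Ly86 by 2.40 ± 0.19 (SE, n = 3 per group; edgeR adjusted p = 0.000454 for both), while Itgax, the integrin CD11c, had 2, 1 and 2 counts in WT and 43, 34 and 37 in rd10. Of 12 complement genes, 10 rose (12 adjusted over the list alone), with a median of 3.21. Serping1, the C1 inhibitor gene, rose by 3.90 ± 0.24 and Cfi, which encodes complement factor I, by 3.33 ± 0.21. The camera adjusted p was 2.94e-22 for microglial and 8.88e-13 for complement genes, and these were the 2 lists called with an estimated correlation as well (adjusted p = 0.0219 and 0.0243). Of 20 genes of antigen presentation and the interferon response, 16 rose (17 adjusted over the list alone), among them B2m (2.54 ± 0.18), Ifitm3 (2.21 ± 0.19) and H2-K1 (1.51 ± 0.14), which shares sequence with H2-D1. The camera adjusted p of this list was 4.65e-13, or adjusted p = 0.14 with an estimated correlation. Of 8 tested cytokine and chemokine genes, 4 rose (5 adjusted over the list alone), namely Csf1 (1.28 ± 0.17), Ccl12 (2, 2 and 3 counts in WT, 20, 16 and 12 in rd10), Cxcl10 (1, 0 and 1 counts, against 15, 9 and 22) and Cxcl16. The camera adjusted p of the cytokine list was 3.47e-05, or adjusted p = 0.0915 with an estimated correlation. Another 10 members of that list, Ccl2, Tnf, Il1b and Il6 among them, had too few counts to be tested.

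Of 16 tested cell death genes, 6 rose (8 adjusted over the list alone). Casp1, the inflammatory caspase gene, had 1, 1 and 6 counts in WT and 37, 24 and 29 in rd10 (log2 fold change 3.56 ± 0.51, and 4.83 without WT-23). Its adaptor gene Pycard rose by 2.08 ± 0.33 and the TNF receptor gene Tnfrsf1a by 1.59 ± 0.26. Bax and Bcl2, chosen after their values were seen, had log2 fold changes of 0.14 ± 0.31 and -0.07 ± 0.23 (edgeR adjusted p = 0.801 and 0.861). Of 17 tested cell cycle genes, 3 rose (3 adjusted over the list alone). Mki67, a proliferation marker, had 1, 3 and 1 counts in WT and 19, 11 and 17 in rd10 (log2 fold change 3.26 ± 0.49, and 3.91 without WT-4). Ccnd2 rose by 0.99 ± 0.16 and E2f1 by 1.21 ± 0.27, the last losing its call without WT-4, Rd10-3 or Rd10-4 (adjusted p = 0.0923, 0.098 and 0.0719) and without both WT-1 and Rd10-4 (0.0557). The camera adjusted p was 0.00033 for cell death and 0.00421 for cell cycle genes, and adjusted p = 0.0915 for both with an estimated correlation. Among genes with a mean of at least 5 CPM, the cell death list had adjusted p = 0.146. Of 13 immediate early genes, Fosb (1.26 ± 0.25) and Egr1 (2.90 ± 0.67) rose, with 3 adjusted over the list alone and a list adjusted p of 0.0515. The list passed without WT-1, WT-23, Rd10-3 or Rd10-5 (adjusted p = 0.00358, 0.0153, 0.0124 and 0.0124), and its median of 0.29 was -0.00215 with inner neuron scaling. Egr1 had 810, 822 and 3954 counts in Rd10-3, Rd10-4 and Rd10-5 against 386, 207 and 182 in WT; its log2 fold change was 1.77 without Rd10-5, and its call was lost without WT-1, WT-4 or WT-23 (adjusted p = 0.088, 0.11 and 0.144) and with the GC trend removed (0.0768). Egr1 also missed the threshold with no filter (0.0595), with Y-linked counts as a factor (0.0909) and without both WT-1 and Rd10-4 (0.145).

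Of 13 vascular and pericyte genes, Kdr, the VEGF receptor 2 gene, rose by 0.92 ± 0.12 and Vwf by 1.44 ± 0.29 (2 adjusted over the list alone), with Vwf at adjusted p = 0.0686 without WT-4. The vascular list had adjusted p = 0.0648, or 0.0177 without WT-1 and 0.0462 without Rd10-3, and a median of 0.14 that was -0.162 with inner neuron scaling. Of 11 genes of the retinal pigment epithelium, the visual cycle genes Rpe65 and Lrat fell by 1.18 ± 0.17 and 1.26 ± 0.26 (2 adjusted over the list alone; list adjusted p = 0.144), with Lrat at adjusted p = 0.0711 without WT-4. Of 8 lens genes, Cryab, a small heat shock protein gene that glia express as well, rose by 1.44 ± 0.18 (1 adjusted over the list alone), and the list had a camera adjusted p of 0.00773, or adjusted p = 0.197 with an estimated correlation, 0.0643 without WT-1, 0.27 without both WT-1 and Rd10-4 and 0.0686 with library size alone. The only tested blood gene, Alas2, had a log2 fold change of -0.50 ± 0.34 (edgeR adjusted p = 0.364), and no library held more than 5 counts of Hba-a1. Of 14 cholesterol synthesis genes 1 was called, and of 16 genes of oxidative phosphorylation Ndufa4 alone fell (-0.77 ± 0.11). Of 18 glycolysis genes, the photoreceptor hexokinase gene Hk2 fell by 0.91 ± 0.19 and the lactate dehydrogenase gene Ldha by 0.58 ± 0.13. Adjusted over the list alone, these 3 metabolic lists had the same counts, and their camera adjusted p were 0.0515, 0.0551 and 0.507. Without WT-23 and without Rd10-3 the cholesterol list passed (adjusted p = 0.0184 and 0.047), as did the oxidative phosphorylation list (0.0157 and 0.0462). Both also passed by fry (adjusted p = 0.0366 and 0.0288), with inner neuron scaling, with no filter and with Y-linked counts as a factor. In all, the cholesterol list passed in 7 of 19 alternatives and the oxidative phosphorylation list in 6 of 19. The medians of the 3 metabolic lists, -0.21, -0.17 and -0.10, turned to 0.0229, 0.0637 and 0.145 with library size alone, as did the -0.18 of the pigment epithelium list (0.0539). The call of Ldha was lost without WT-4, Rd10-3, Rd10-4 or Rd10-5 (adjusted p = 0.0683, 0.104, 0.0559 and 0.0513), with library size alone (0.0798), against a fold of 1.2 (0.0652) and with Y-linked counts as a factor (0.0556). The call of Hk2 was lost without Rd10-3 or Rd10-4 (adjusted p = 0.0667 and 0.0545).

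**Figure D3:**
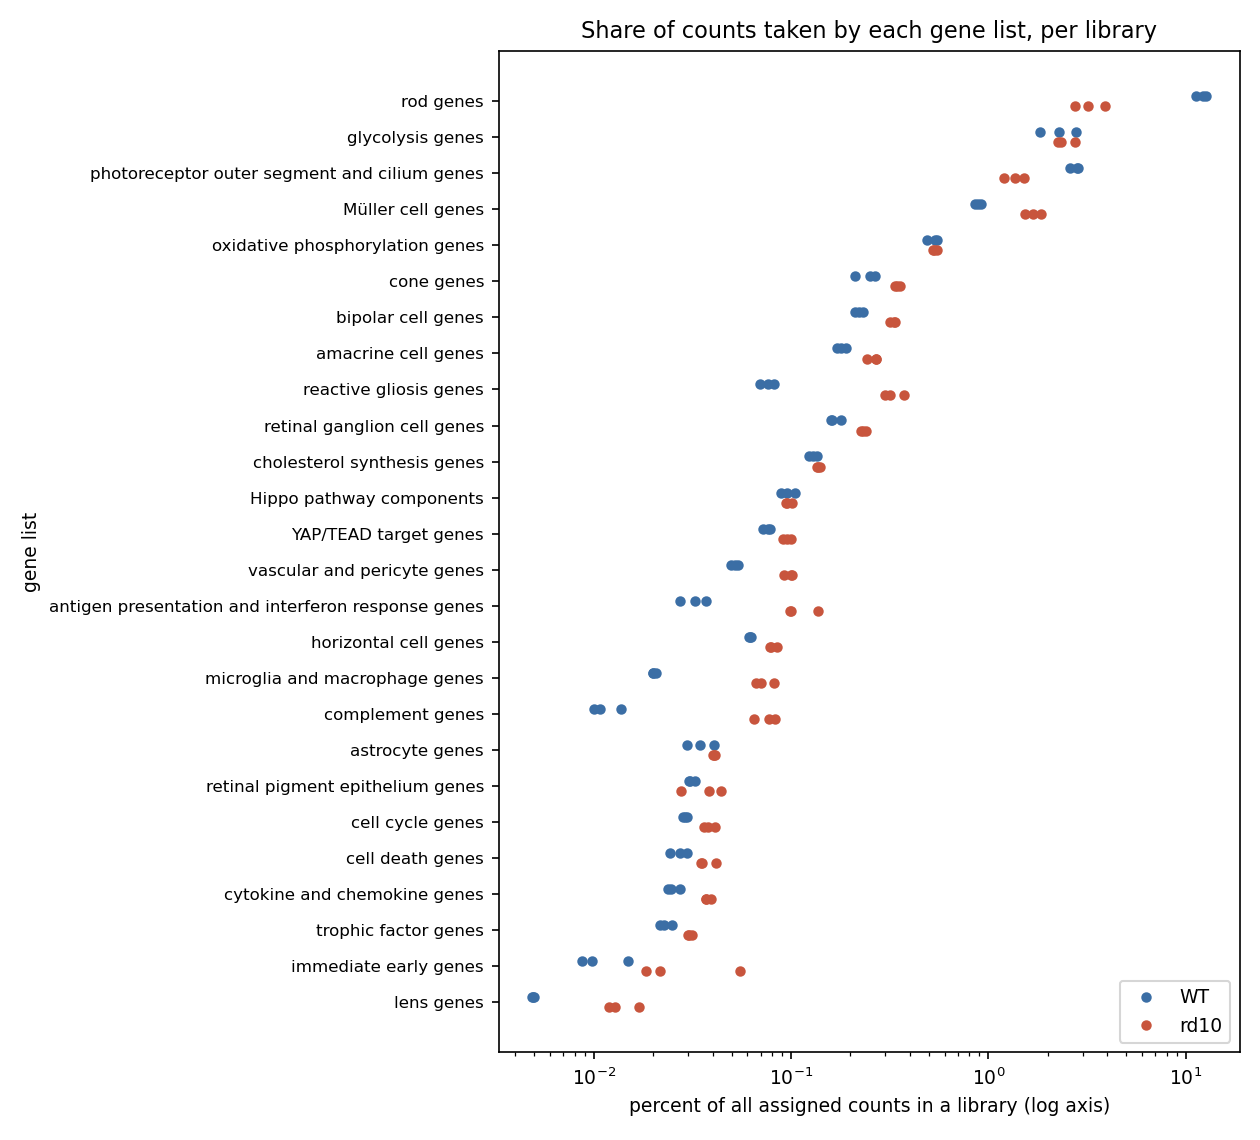
Percent of all assigned counts (x axis, log scale) taken by each gene list (y axis) in the WT libraries (blue) and the rd10 libraries (red), with a dot per library. Rod genes took a mean of 12.1% in WT and 3.28% in rd10, and microglia and macrophage genes 0.0202% and 0.0729%.

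The authors deposited gene tables of their own for rd10 over WT. The larger of the authors' deposited tables held 3427 genes, 1449 with higher and 1978 with lower values in rd10, and no p above 0.0499 and no log2 fold change smaller in size than 0.264. Of the 3419 genes of the authors' deposited table that were tested here, all 3419 had the same direction in the count fit, 1712 (50.1%) were called, and 3348 had an unadjusted p under 0.05 with a fold of at least 1.2. The count fit called 296 genes that the authors' deposited table did not hold. In the authors' deposited table Yap1 went from an FPKM of 7.4 to 10 (p = 0.0227), Tead2 from 2.3 to 4.0 (p = 0.0126), Ctgf from 24.9 to 47.0 and Cyr61 from 7.1 to 14.1. These 4 genes were also in the smaller of the authors' deposited tables, a selection named for the inner nuclear layer with 293 genes, 154 higher and 139 lower, all of them in the larger one. Of its 292 tested genes, 130 were called, 79 higher and 51 lower, and 282 passed at an unadjusted p under 0.05 with a fold of at least 1.2. The study chose both tables on these samples, so they are not independent evidence of direction.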

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

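The GC trend, the factor for Y-linked counts, the fit without WT-1 and Rd10-4 and the changes of list members were chosen after the results were seen. No paired analysis was possible because the numbers in the count columns match no replicate numbers of the labels; the planned share without mitochondrial genes and the planned test of FPKM were not run, since the table holds no mitochondrial genes and FPKM is given once per group. Of 1611 alternative values of the 78 genes chosen by rule, 1529 kept direction and side of the threshold, 66 lost the call and 12 gained it. Another 4 changed sign, all with inner neuron scaling: Wwtr1 (-0.1912), Tead1 (-0.08609), Glul (-0.0117) and Gad1 (-0.08179). Gad1 is itself among the genes that set these factors. The 2008 called genes (990 higher, 1018 lower) became 3037 (2465 and 572) with library size alone, 4505 (630 and 3875) with inner neuron scaling, 881 (439 and 442) at an adjusted p under 0.01, 1285 (662 and 623) against a fold of 1.2, 4158 (1952 and 2206) at an unadjusted p under 0.05 with that fold, and 4545 (2293 and 2252) with the GC trend removed. Leaving out 1 library gave 885 to 3214 (474 to 1553 higher, 411 to 1661 lower), with fewer samples in each fit. DESeq2 called 2424, the fit with Y-linked counts 1442 and that without WT-1 and Rd10-4 2696, and no gene called in both changed sign under any alternative. With an estimated correlation the called lists went from 16 to 2, and rod (0.0918), Müller (0.0915), gliosis (0.0915) and YAP/TEAD target genes (0.279) passed no more. Their estimated correlations of 0.529, 0.0993, 0.256 and 0.13 lay above the preset 0.01. Bipolar, amacrine and cell cycle genes lost their calls too, with estimated correlations of 0.00796, -0.0173 and -0.0519, below the preset. A higher correlation between members is thus argued against for these last lists. Camera's adjusted p also rose for called lists with small estimated correlations. For microglial genes (0.0226) it went from 2.94e-22 to 0.0219, and for complement genes (0.0114) from 8.88e-13 to 0.0243. Member correlation alone thus does not account for the drop from 16 to 2 lists. How much it adds for rod, Müller and gliosis genes was not tested. For uncalled lists, the direction of Hippo components changed with fry (0.924), without WT-1 (0.715) and without WT-1 and Rd10-4 (0.88), and that of glycolysis genes without WT-1 (0.701); leaving out 1 library gave adjusted p of 0.386 to 0.897 and 0.0756 to 0.726 for these lists. The unadjusted threshold raised the overlap with the authors' tables from 1712 to 3348 and from 130 to 282. In the simulation, run at 1 depth and with 3 libraries per group, 7.895% of 1.5-fold changes were recovered, and how much of this the depth limits was not tested.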

Other observations

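Except for the count over splits with the GC trend left in, which was planned, the tests in this part were chosen after the results were seen. The authors' deposited table gives a PANTHER protein class for 1918 of its genes, 47.4% of them higher in rd10. Some receptor and adhesion classes held mostly higher genes, among them 53 of 61 G-protein coupled receptors, 27 of 31 members of the immunoglobulin receptor superfamily, 20 of 21 cadherins and 44 of 59 cell adhesion molecules (Fisher's exact test against the other genes of the table, adjusted p = 6.31e-09, 6.87e-05, 6.87e-05 and 0.000266 over 70 classes). Cell adhesion molecules of the immunoglobulin superfamily (13 of 18 higher) and cell junction proteins (15 of 22) did not pass (adjusted p = 0.11 for both). Of the classes that held mostly lower genes, those with the smallest p were 41 of 46 chromatin-binding proteins, 32 of 36 KRAB box transcription factors, 33 of 38 ribosomal proteins and 21 of 23 mRNA splicing factors (adjusted p = 4.16e-06, 6.87e-05, 0.000114 and 0.000796). Helicases (26 of 31 lower), RNA binding proteins (24 of 29), RNA helicases (16 of 18) and DNA binding proteins (23 of 29) passed as well (adjusted p = 0.00211, 0.00504, 0.00691 and 0.0148). Nucleic acid binding, with 51 higher and 52 lower genes (adjusted p = 0.796), zinc finger transcription factors, with 12 and 17 (0.685), and DNA helicases, with 4 and 11 (0.219), did not pass, nor did transcription factors (33 and 58, 0.076) and transcription cofactors (13 and 30, 0.0737). Fewer of these passed the count fit over all genes, with 28 higher and 3 lower receptors of the first class, 23 lower and 1 higher chromatin-binding proteins, 10 lower KRAB factors and 12 lower and 1 higher ribosomal proteins. The directions are those of the authors' deposited table, and classes share members. Genes are not independent replicates, so these p-values do not measure the spread between samples. The balance of higher and lower genes also depended on the scaling. In the count fit, 14% of calls were higher with inner neuron scaling and 81.2% with library size alone. In the selection named for the inner nuclear layer, 172 of 293 genes had a transcription class, of 224 such genes in the larger table, and 55 a receptor class.

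Müller, gliosis and some YAP/TEAD target genes rose while the share of rod counts fell, and a lower rod share alone would raise genes of every other cell type alike. The rise exceeded that of the mean of inner neuron genes by 0.362 ± 0.043 for Müller and 2.02 ± 0.15 for gliosis genes (log2, SE). For Ctgf the excess was 0.667 ± 0.233 and for Cyr61 0.749 ± 0.217. Each value lay over 2 SE, with an exact permutation p = 0.1, the smallest possible with n = 3 per group. For Müller and gliosis genes, at 8.43 and 13.3 SE, the values argue against that explanation. For Ctgf and Cyr61 they lay at 2.86 and 3.46 SE, which with n = 3 per group does not decide it for single genes. Cyr61 also lost its call with inner neuron scaling. Microglial (1.77 ± 0.09) and astrocyte genes (0.303 ± 0.112) exceeded inner neurons by over 2 SE too, unlike vascular (0.0472 ± 0.109) and horizontal cell genes (-0.088 ± 0.0521); for Müller and gliosis genes the excess held with the GC trend removed as well (0.386 ± 0.054 and 2.02 ± 0.15), while Ctgf and Cyr61 had no GC content matched by symbol and were not corrected. For the YAP/TEAD list (0.0113 ± 0.0663, or 0.173 ± 0.067 without Nt5e and Lats2, which were left out after their values were seen and whose removal raises it by construction) and for Yap1 (0.175 ± 0.211, and 0.243 ± 0.080 with the GC trend removed) it stays open, since list members moved both ways and the values of Yap1 lie on both sides of 2 SE. Yap1 may also follow the share of Müller RNA, from which its change differed by -0.187 ± 0.191 (-0.143 ± 0.1 with the GC trend removed). So may Ctgf (0.305 ± 0.205) and Cyr61 (0.387 ± 0.226), and with each value within 2 SE none decides it. The same difference was -0.367 ± 0.284 for Tead1 and -0.492 ± 0.179 for Wwtr1 (-0.43 ± 0.073 with the GC trend removed). Wwtr1 thus stayed over 2 SE below the Müller change (exact permutation p = 0.1, the smallest possible), and neither Wwtr1 nor Tead1 was called.

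The first axis of variation (57.3% of variance) parted the genotypes, and the second (26.6%) placed WT-1 (41.2) and Rd10-4 (22.9) apart from WT-4 (-4.79), WT-23 (-27.7), Rd10-3 (-13.5) and Rd10-5 (-18.0), so genotype does not account for it. Across genes, which are not independent replicates, loadings on this axis followed transcript GC content (Spearman correlation 0.77), and a GC bias of single libraries is a candidate explanation. Sex stays open, since the overlap on this axis of libraries with and without Y-linked counts (gap of -22.95) rests on WT-23 alone (gap of 27.7 without it), and so does a different mix of cells in the dissected retinas. Removing the trend raised the called genes from 2008 to 4545 and brought Yap1 (0.49 ± 0.10, adjusted p = 0.00387, range 0.00387 to 0.612 over its alternatives) and Glul (0.31, adjusted p = 0.023, range 0.0115 to 0.947) under the threshold. What set these libraries apart at the bench was not tested.

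Hdc and Glb1l3 fell further than any tested gene of the rod list, whose median log2 fold change was -2.09. They were picked for the size of their falls and had few counts left in rd10 (2, 3 and 3 for Hdc, and 2, 0 and 7 for Glb1l3), so loss of rods alone stays open. Sequence of another strain, carried along with the Pde6b allele on chromosome 5, is argued against as a change within the genes themselves. Hdc lies on chromosome 2 and Glb1l3 on chromosome 9. The falls may still come from such sequence acting on genes of other chromosomes, or from strain sequence elsewhere in the genome. Lower transcription in the surviving rods may account for them as well, and none of these was tested.

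By edgeR, 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave 2008 called genes, and the highest of the others gave 5; with the GC trend removed the real split gave 4545 and the highest other 5, again 1 of 10. With 10 splits the share cannot fall under 0.1. Every other split mixes the genotypes, so the genotype difference widens the spread within its groups and lowers its calls. The low counts of the other splits are therefore no measure of chance. The split that gave 5 calls put WT-1, WT-23 and Rd10-4 together. These 3 libraries had 1643, 2659 and 821 counts of Xist, and 0, 0 and 1 counts of Y-linked genes, while WT-4, Rd10-3 and Rd10-5 had 3, 2 and 7 counts of Xist and 2160, 1663 and 1801 Y-linked counts; the labels do not give the sex. Within 10 Mb of Pde6b, 29 of 166 tested genes were called (17.5%), against 14.4% elsewhere (Fisher's exact test, p = 0.266). In the larger of the authors' deposited tables, symbols of 6 genes had the form of dates.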
